A study of Rattus norvegicus with 6 samples.

How the data were processed

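The samples were 6 RNA-seq libraries of differentiated rat trophoblast stem cells, 3 with control shRNA and 3 with Foxo4 shRNA, grouped by the shRNA named in the labels. The labels do not say whether the 3 samples of a group came from separate infections or cultures, so the authors' p-values may measure technical spread only. The sample titles of the 2 groups are written in different ways, and whether this marks different batches is not given in the sources used here.

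Per the labels' protocols, total RNA was isolated with TRIzol, libraries were made with Illumina TruSeq kits and sequenced as 100-bp paired-end reads on a NovaSeq 6000, and reads were mapped to the rat genome (Ensembl Rnor_5.0.78) with CLC Genomics Workbench 12.0. The labels' protocols further state that abundance was expressed as TPM and that a P value of 0.05 was the limit for differential expression. The submitters' processing notes name the genome build Rnor_5.0. The authors' deposited table holds no TPM: per the file headers it gives a fold change and a p-value per feature. The fold change deposited by the authors is linear and signed, with no value between -1.5 and 1.5, so a negative value is minus the reciprocal of a ratio whose numerator the header does not name; the direction was assumed from the negative sign of Foxo4. The p-value deposited by the authors is not described further: which test gave it, and whether it was adjusted for multiple testing, is not given in the sources used here. For 445 features the value equals that of an exact test without adjustment, as described below. The 703 features carry gene names with a number, which look like transcripts, and 51 of the 647 gene names have more than 1 feature.

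The test planned before the data were examined, limma on log2(TPM + 1), needs values per sample and was not run. As planned for that case, no test between the samples was made, the authors' fold changes and p-values are described as theirs, and counts are of listed features. Changes were counted by direction among features and among gene names, where a gene is represented by its feature with the largest change. The 24 gene lists were fixed before the data were examined. Listed members were counted by the exact symbol in the table. For lists with at least 5 listed members the number of higher members was set against the split of all listed genes. The test was an exact two-sided binomial test, with Benjamini-Hochberg adjustment over the 5 lists tested. It takes the members of a list as independent, which co-regulated genes are not, and it measures no spread between samples. Because the table holds selected features only, no enrichment against all genes was made, and a count adjusted over the list alone cannot be formed. Genes were named by a rule fixed in advance: Foxo4; the 8 largest increases and the 8 largest decreases, leaving out predicted-locus symbols; up to 3 members with the largest change per list; and Foxo1 and Foxo3 where listed. Other listed members of the lists are named to account for each count. The rule's condition on level and on agreement of the replicates applies only where such values exist.

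The number of reads behind a feature is not in the table, but the listed p-values carry information on it. An exact two-sided test of 2 equal groups with whole reads can give only certain p-values, and 445 of the 703 listed p-values (63.3%) equal 1 of them within a relative tolerance of 5e-09 when the spread beyond counting error is practically 0. That spread was a single value fitted to the listed p-values themselves. In 100 copies of the p-values shifted by a small factor, at most 3 matched. The spread was not fitted again for these copies. For these features the matching split of reads is given as the reads of the 2 groups; the total over both groups had a median of 82 and a range of 6 to 236 reads. Among the 388 matched features with 5 or more reads in each group, the read ratio lay within 0.1 of the listed log2 fold in 373. The reads may have been scaled to a common library size before the test, so they are reads per group on that scale. Where 1 group has 0 reads, the fold is given against a floor of 3 reads over the group. Such a fold takes the other group's reads as exact and is not a lower confidence limit. Intervals of read ratios are exact 95% (Clopper-Pearson) intervals. Floors and intervals cover no error beyond counting. The depth per sample is unknown.

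Gene names were looked up in a RefSeq gene table of the GRCr8 assembly, which differs from the authors' build and was used only to see which genes share a chromosome and how they are ordered: 591 of the 647 gene names matched, and 589 genes with 1 direction were placed. Directions were compared between each of 21 chromosomes and the rest with a two-sided Fisher exact test and Benjamini-Hochberg adjustment, and the median change of higher genes with a permutation test of 100000 resamples. The read recovery was tested on simulated data: all 303 simulated features with counting error alone were matched with the right split, and 0 of 200 with added spread. On 2000 simulated lists of 10 genes the list test without adjustment called 4% at random directions and 81.2% with nearly all genes lower. These shares do not hold for the adjusted p used here. On 200 simulated families of 21 chromosomes without an effect, the chromosome test made a call in 4%. Alternatives were another fold limit, and stricter p-values, an adjusted p, gene names, older symbols, an even split, assumed spreads and a count without 1 chromosome, all but the fold limit on the count and share of features chosen after the data were seen. The computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.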

Results

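RNA sequencing compared rat trophoblast stem cells, the proliferative precursors of the placental trophoblast lineages, that carried a lentiviral control shRNA with cells that carried a shRNA against Foxo4, a forkhead transcription factor that the kinase AKT phosphorylates. The series title sets the experiment within an AKT1-FOXO4 axis in placentation, and the comparison asks which transcripts differ in differentiated trophoblast when Foxo4 is knocked down. The cells came from Holtzman Sprague-Dawley rats, were selected with puromycin and were collected on day 15 of differentiation, with 3 control shRNA samples and 3 Foxo4 shRNA samples. The values analysed here are the authors' own comparison of the 2 groups, 1 fold change and 1 p-value for each of 703 features, so no value per sample, depth per sample or spread between replicates stands behind the numbers below. The authors' deposited table held only features with a change of at least 1.5-fold and a p-value under 0.05, and a gene that is absent from it was either unchanged, below these limits or not measured. Its header does not say which group is the numerator, and changes are given below as Foxo4 shRNA relative to control shRNA because both Foxo4 features carried a negative sign. All fold changes and p-values of single genes below are the authors'.

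The authors' deposited table held 2 Foxo4 features, Foxo4_1 with a 2.24-fold and Foxo4_2 with a 1.96-fold difference between the groups, both of the same sign and each with a listed p-value of 0. Since this sign set the direction of all changes given here, that Foxo4 was lower is an assumption, and the table gives no separate check of the knockdown or of the labels. Of the other FOXO genes, it listed 1 feature of Foxo3 as 3.61-fold lower at a p-value of 0.0192, which is that of 15 reads against 4, and it did not list Foxo1. The list of PI3K, AKT and FOXO pathway genes had no other listed member among its 26 genes.

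The 2 directions were unequal in number. In the authors' deposited table, 443 features had the sign of Foxo4, read here as lower, and 260 the other, read as higher, so that 37.0% were higher (63.0% if the ratio is turned), with a median change of 1.88-fold among the lower and 1.79-fold among the higher features. The features belonged to 647 gene names, of which 399 were lower, 245 were higher and 3 (Tpm1, Hiatl3 and AABR07031445.1) had features in both directions. At 2-fold or more, 186 features were lower and 90 were higher. The largest increases with a gene symbol in the authors' deposited table were Psmb7 (132-fold), which encodes a proteasome subunit, Crx (27.8-fold), Scn1b (23.0-fold), Rpl3 (19.6-fold), Coa8 (19.3-fold), Smarcb1 (17.5-fold), Msn (16.5-fold) and Zfp84 (14.9-fold). The largest decreases in the authors' deposited table were Ndufv3 (33.9-fold), Ppp3r1 (32.7-fold), Ntan1 (30.3-fold), Commd4 (30.1-fold), Pigu (29.3-fold), Gpx3 (21.8-fold), Prkar2b (20.9-fold) and Nsmaf (19.95-fold). Each of these values belongs to a single transcript-like feature of its gene, and further features of Rpl3 (1.69-fold higher) and Ntan1 (1.65-fold lower, 70 reads against 42) in the authors' deposited table changed far less. For 8 of these 16 genes the listed p-value was that of reads in 1 group against 0 in the other. Their listed folds thus have no upper bound from the reads. Against a floor of 3 reads over the group, Crx was 4.33-fold, Scn1b 2.67-fold and Zfp84 2-fold higher. Ndufv3 and Ppp3r1 were 4-fold, Pigu 3.67-fold and Prkar2b and Nsmaf 2.33-fold lower against that floor. These values are not lower confidence limits, because the reads of the other group carry counting error too. Smarcb1 rested on 27 reads against 1, a read ratio of 27 with an exact 95% interval of 4.45 to 1105. No reads were recovered for the remaining genes. Their p-values in the authors' deposited table were 6.27e-38 for Gpx3, 6.13e-27 for Psmb7 and 3.65e-05 for Rpl3. They were 0.000292 for Msn, 0.00107 for Ntan1, 0.00136 for Commd4 and 0.0251 for Coa8, so large folds of this kind can rest on weak p-values.

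Of the 23 genes of the prolactin (PRL) family, whose members are hormones of the rodent placenta, 8 were listed, 5 higher and 3 lower. In the authors' deposited table Prl3d2 was 4.11-fold higher at a p-value of 5.72e-24 and Prl3d1, a hormone of trophoblast giant cells, was 3.32-fold higher at a p-value of 2.13e-17. Prl2c1 was listed as 2.26-fold, Prl5a1 as 1.90-fold and Prl4a1 as 1.54-fold higher in the same deposited table of the authors. The lower members in the authors' deposited table were Prl8a5, with 3 features between 2.24-fold and 3.30-fold lower, Prl8a2 (2.30-fold) and Prl8a3 (2.27-fold). No difference between the direction of the PRL family and that of all listed genes was detected (exact two-sided binomial test, adjusted p = 0.350). Reads can be shared among those PRL, CEACAM and PSG genes that are close copies of each other. How the authors' mapping assigned such reads is not given in the sources used here.

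Of the 18 genes on the trophoblast giant cell list, 4 were listed. The authors' deposited table had Prl3d1 and Prl2c1 higher, Hand1, a transcription factor of giant cell differentiation, 1.59-fold higher at a p-value of 1.94e-09, and the placental cathepsin Ctsr 2.22-fold lower at a p-value of 0.0161. Of the 23 spongiotrophoblast and glycogen cell genes, 7 were listed, 4 lower and 3 higher, with no detected difference from the split of all listed genes (exact two-sided binomial test, adjusted p = 1). Tpbpa, the usual marker of the junctional zone, was 3.22-fold lower at a p-value of 6.66e-16 in the authors' deposited table, together with Ceacam12 (7.22-fold), Ceacam11 (6.71-fold) and Psg29 (2.92-fold). The higher members in the authors' deposited table were Ceacam3 (2.70-fold), Ceacam9 (2.52-fold, p-value 9.25e-20) and Phlda2 (1.89-fold). Of the 19 invasive trophoblast genes, 4 were listed, of which the authors' deposited table had the metalloproteinase gene Mmp12 3.53-fold, Ceacam9 2.52-fold and Prl5a1 1.90-fold higher and the keratin gene Krt7 1.84-fold lower. Among 14 syncytiotrophoblast genes Ly6e alone was listed, with features 3.22-fold and 1.59-fold higher in the authors' deposited table. Of the 18 stem state genes, Id1 (1.88-fold) and Fgfr2 (1.85-fold) were listed, both as higher, in the authors' deposited table.

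**Figure D1:**
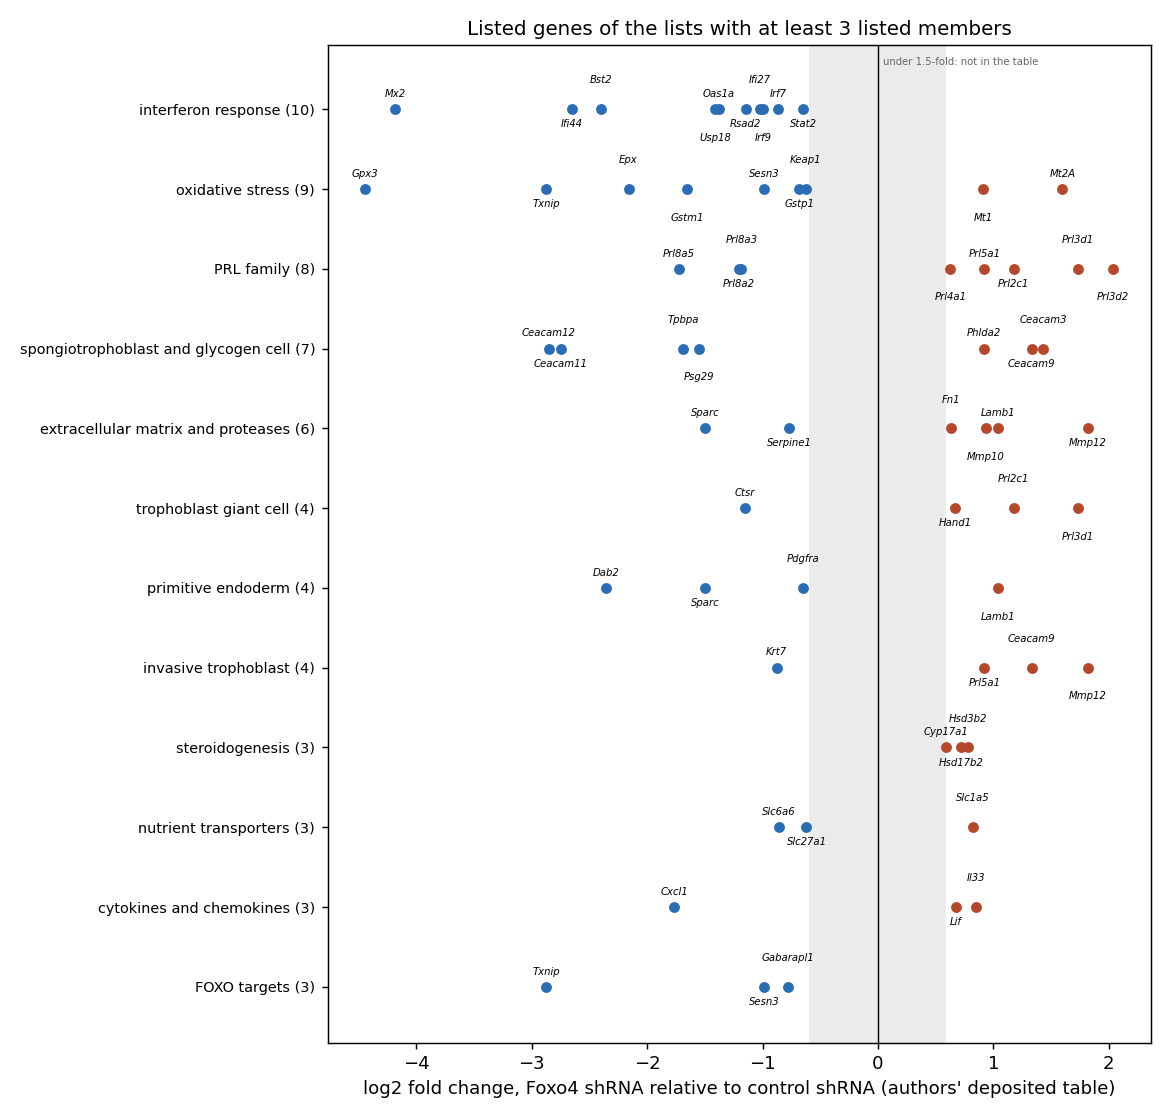
The plot shows each listed gene of the 12 fixed lists with at least 3 listed genes, in rows with the number of listed genes in brackets; the x axis is the authors' log2 fold change of Foxo4 shRNA relative to control shRNA, blue for lower and red for higher, for the feature of each gene with the largest change, with no error because the table gives none. All 10 interferon response genes lie to the left of 0, while the PRL family has 5 genes on the right and 3 on the left; the point of Mx2 is the listed fold, which rests on 13 reads against 0.

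Steroid hormone synthesis genes were listed in 1 direction. Of 17 genes, 3 were listed, and in the authors' deposited table Hsd3b2, which encodes a 3-beta-hydroxysteroid dehydrogenase, was 1.72-fold higher at a p-value of 4.52e-17, Hsd17b2 1.65-fold higher and Cyp17a1 1.503-fold higher. Hsd3b2 also belongs to a family of close copies.

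Some known FOXO targets and antioxidant genes were among the transcripts listed as lower. Of 34 FOXO target genes, 3 were listed, all lower, which is too few for a test. Most listed genes were lower too (399 of 647 gene names). The authors' deposited table had Txnip, a thioredoxin-binding protein, 7.32-fold lower at a p-value of 6.14e-25, the stress-response gene Sesn3 1.98-fold lower at a p-value of 8.31e-07 and the autophagy gene Gabarapl1 1.72-fold lower at a p-value of 8.85e-06. Of 48 oxidative stress genes, 9 were listed, 7 lower and 2 higher. There was no detected difference from the split of all listed genes (exact two-sided binomial test, adjusted p = 0.622). The 7 lower genes include Txnip and Sesn3, which were counted among the FOXO targets too. In the authors' deposited table Gpx3, the secreted glutathione peroxidase, was 21.8-fold lower at a p-value of 6.27e-38, the smallest above 0, and Gstm1 was 3.15-fold lower at a p-value of 1.84e-23. Epx was 4.47-fold, Gstp1 1.60-fold and Keap1 1.54-fold lower in the authors' deposited table, and the metallothioneins Mt2A and Mt1 were 3.03-fold and 1.88-fold higher.

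The interferon response list had the most listed members by number, though not as a share of its genes, and each of them was lower. Of 32 genes, 10 were listed, all 10 lower, with an exact two-sided binomial p of 0.0170 against the split of all listed genes. The adjusted p was 0.0851 over the 5 lists tested, which does not pass 0.05. All 10 lower is the most extreme lower outcome for 10 genes. Given the p-values of the other tested lists, no lower split of this list could have passed. The test also takes the genes as independent. The authors' deposited table had Bst2 5.27-fold lower at a p-value of 6.21e-07, Usp18 2.66-fold, Ifi27 2.03-fold at a p-value of 2.77e-08 and Irf9, a subunit of the interferon-activated transcription complex, 1.99-fold lower at a p-value of 1.33e-05. Also lower in the authors' deposited table were Oas1a (2.60-fold), Rsad2 (2.21-fold), Irf7 (1.82-fold) and Stat2 (1.56-fold). Mx2 and Ifi44 rested on few reads. In the authors' deposited table the p-value of Mx2 was that of 13 reads against 0, or 4.33-fold lower against the floor of 3 reads. A second feature of Mx2 was 2.18-fold lower on 21 reads against 9. The p-value of Ifi44 was that of 11 reads against 1. The read ratio of Ifi44 was 11, with an exact 95% interval of 1.60 to 473 that covers counting error only. Of 29 cytokine and chemokine genes, the authors' deposited table listed Cxcl1 as 3.40-fold lower, Il33 as 1.80-fold higher and Lif as 1.60-fold higher.

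Genes of the extracellular matrix and its proteases went both ways. Of 37 genes, 6 were listed, 4 higher and 2 lower (exact two-sided binomial test, adjusted p = 0.350). In the authors' deposited table Mmp12 was 3.53-fold higher at a p-value of 5.58e-13, the laminin gene Lamb1 2.05-fold, Mmp10 1.91-fold and Fn1, which encodes fibronectin, 1.55-fold higher, while the matrix protein gene Sparc was 2.83-fold lower and Serpine1 1.71-fold lower. Among 27 hypoxia and glycolysis genes the authors' deposited table listed Vegfa, with features 1.80-fold and 1.77-fold higher. Fn1 and Vegfa lie on a chromosome on which 46 of 47 listed genes were higher, against 172 of 542 listed genes on all other chromosomes (two-sided Fisher exact test, p = 3.45e-19 adjusted over 21 chromosomes, chosen after the values were seen).

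**Figure D2:**
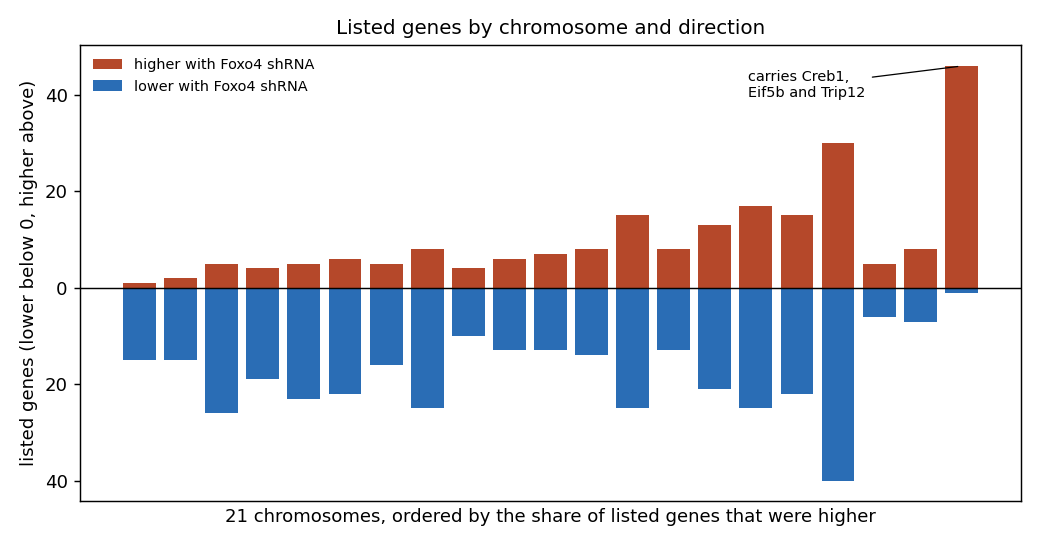
Bars give the number of listed genes that were higher (red, above 0) and lower (blue, below 0) on each of 21 chromosomes, which are unnamed and ordered along the x axis by the share that was higher. The chromosome at the right, which carries Creb1, Eif5b and Trip12, had 46 higher genes and 1 lower gene, and on the others at most 53.3% of the listed genes were higher. The direction is assumed from the sign of Foxo4, and with the ratio turned higher and lower would change places.

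Of 26 nutrient transporter genes, the authors' deposited table listed the glutamine transporter gene Slc1a5 as 1.77-fold higher and Slc6a6 (1.81-fold) and Slc27a1 (1.54-fold) as lower. Of 26 apoptosis genes, it listed Casp7 as 2.15-fold lower and 1 feature of Birc3 as higher. The p-value of Birc3 was that of 7 reads against 0, which is 2.33-fold against the floor of 3 reads. Lists of markers of other cell types had listed members too. In the authors' deposited table, 2 of 18 mesenchymal genes (Col5a1, 1.66-fold, and Pdgfra, 1.57-fold) and 1 of 15 leukocyte genes (Csf1r, 3 features between 1.88-fold and 2.49-fold) were lower. Of 16 primitive endoderm genes, 4 were listed, with Dab2 (10 reads against 2, p-value 0.0386), Sparc and Pdgfra lower and Lamb1 higher in the authors' deposited table. The read ratio of Dab2 was 5, with an exact 95% interval of 1.07 to 46.9. Csf1r is also expressed in trophoblast. No gene was listed from the lists of cell cycle (0 of 36), cholesterol synthesis (0 of 20), integrated stress response (0 of 19), endothelial cell (0 of 12) and erythroid cell genes (0 of 12), which does not show that these genes did not change.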

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

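The fold limits on the count and share of features were chosen before the data were examined; the 2-fold limit on the lists and the named genes, the stricter p-values, the adjusted p, gene names in place of features, features in place of genes for the lists, older symbols, the even split, the assumed spreads, the splits without features with 0 reads and the counts without 1 chromosome were chosen after the data were seen. No paired analysis was possible because the deposited table holds 1 fold change and 1 p-value per feature and no value per sample. For the same reason other pseudocounts, scalings, variance models and filters on level, an adjusted p of the authors, set tests and leaving out a replicate were not run.

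Of 703 listed features, 276 were left at 2-fold or more, 498 at a p under 0.01 and 342 at a p under 0.001. Adjusting the p-values with all 114725 RefSeq transcripts as tests left 239. Each count is smaller because its limit is stricter. The adjustment ranked the listed features only, without those of small p under 1.5-fold, so its count can be too low. The transcripts are those of GRCr8, which differs from the authors' build. The share of higher features fell from 37.0% to 32.6% at 2-fold or more and to 32.3% without the chromosome that carries Creb1, Eif5b and Trip12, and it was 36.5% to 38.0% in the 4 other settings; with the ratio turned the first 3 values are 63.0%, 67.4% and 67.7%. The adjusted p of the interferon response list, 0.0851, was 0.0319 with features in place of genes and 0.00977 against an even split, and it ranged up to 0.416 at 2-fold or more. Features in place of genes counted Mx2 and Bst2 once per feature, and features of the same gene are not independent. The even split ignores that fewer listed genes were higher than lower. Neither smaller value is therefore stronger evidence. For the 4 other tested lists no adjusted p passed 0.05 in the alternatives run, and the smallest was 0.315; the extracellular matrix list had too few listed genes for a test at 2-fold or more. The second Foxo4 feature had the sign of the first, which set the direction of the table. Of the 445 features with recovered reads, 405, 296 and 114 would have a p under 0.05 at an assumed coefficient of variation between libraries of 0.1, 0.2 and 0.4.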

Other observations

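Apart from Col5a1 and Pdgfra, the genes of this paragraph and the next lie outside the fixed lists; they were chosen after their values were seen, so they are single values and no test of a group. In the authors' deposited table, lower genes with products in collagen and matrix assembly were Serpinh1, the collagen chaperone (features 2.99-fold and 2.13-fold lower), Efemp2 2.51-fold, Loxl2 1.98-fold and 1.56-fold, Loxl4 1.83-fold and Fbln1 1.64-fold. The 2 listed genes of the mesenchymal list, Col5a1 (1.66-fold) and Pdgfra (1.57-fold), were lower with them in the authors' deposited table. The collagenase genes Mmp1 (2.84-fold, p-value 6.45e-07) and Mmp1b (2.80-fold, 17 reads against 6) and Mmp24 (1.71-fold) were higher in the authors' deposited table, and Mmp19 was 1.55-fold lower. Lower genes with products in lipid or glycogen metabolism in the authors' deposited table were Srebf1, a regulator of fatty acid synthesis (2.69-fold), Pltp (1.92-fold), Cpt1a (1.68-fold) and Ppp1r3b, a glycogen-targeting subunit of protein phosphatase, by 2 features 11.2-fold (26 reads against 2, exact 95% interval of the ratio 3.25 to 113) and 7.12-fold lower (30 reads against 4); a feature of Abcg1 was 12.3-fold lower (41 reads against 3, exact 95% interval of the ratio 4.36 to 69.0).

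The authors' deposited table also had Pappa2, a protease of insulin-like growth factor binding proteins, 3.84-fold and 3.34-fold lower, the protein C receptor gene Procr 3.40-fold lower at a p-value of 2.49e-28 and Egfr 2.34-fold lower. The placental cathepsins Cts7 (2.52-fold) and Cts8 (1.94-fold) and the steroid gene Hsd3b3 (2.18-fold and 2.10-fold) were higher in the authors' deposited table, as were Myc (1.91-fold, p-value 1.54e-08), Hoxb4 (2.90-fold), Hoxa3 (2.82-fold) and Hoxb9 (1.76-fold), the HOX genes each on 24 or fewer reads against 8 or fewer except Hoxb9 (33 against 18).

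In the 3 paragraphs that follow, the direction test of the interferon list was chosen before the data were examined and the other tests after the patterns had been seen.

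On 1 chromosome, which carries Creb1 (1.91-fold higher), Eif5b (1.56-fold) and Trip12 (1.52-fold) in the authors' deposited table, 46 listed genes were higher and 1, Des, was lower. Chance placement is argued against by the Fisher exact test (p = 3.45e-19 adjusted over 21 chromosomes; no other chromosome was under 0.0827), and a local cluster or reads shared among neighbours by the spread of the higher genes over 9 of 10 equal parts of its gene order. A candidate explanation is a higher copy number of this chromosome in some or all of the Foxo4 shRNA cells: dosage raises genes by a like, modest factor, and the higher genes had a median of 1.60-fold there against 1.81-fold elsewhere (permutation test, p = 0.00193), but any other cause that raises the chromosome's genes modestly gives the same, and if the ratio is turned the higher copy number would lie in the control cells. The share of expressed genes that moved is unknown, since the table lists 4.91% of the chromosome's 936 protein-coding genes as higher and omits changes under 1.5-fold. A response to Foxo4 knockdown was not tested, because the cell population and the shRNA are the same split of the samples; genotyping or DNA copy number of both populations would tell.

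Of the listed p-values, 445 equal those of whole reads with practically no spread beyond counting error. In 100 shifted copies at most 3 did, which argues against a coincidental match. The copies were scored at the spread fitted to the listed values. Values adjusted for multiple testing would not match in this way, so the matched p-values are read as unadjusted. A candidate explanation of the matches is a spread estimate at its lower limit for features with few reads. Among 490 features whose fold and p imply 200 reads or fewer, 425 matched. Of 94 that imply more than 300, 0 matched (two-sided Fisher exact test, p = 8.90e-66). Both bounds were chosen after the matches, which had at most 236 reads, were seen, so this p-value is descriptive only. Features between the bounds or without an implied number were left out. Libraries of a group that differ by counting error alone, as repeat libraries of 1 culture would, stay open. The 0 matches above 300 reads can also come from another calculation for high counts. That calculation would not account for the features that imply 200 reads or fewer and did not match. In both cases the p-values of the matched features leave out any variation between cultures, and no biological explanation was tested.

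The 10 listed interferon response genes were all lower, and outside the list so were Oas1f (2.37-fold), Oas1i (3.37-fold), Apol9a (3.45-fold) and Ifi27l2b (1.83-fold), whereas Plscr1 (2.87-fold and 2.27-fold) and Parp9 (1.73-fold), also interferon-inducible, were higher in the authors' deposited table. Calls on a handful of reads do not account for it, since 7 of the 10 need more than 50 reads to give their fold and p. Chance direction was not excluded (exact two-sided binomial test, adjusted p = 0.0851). The adjusted test could not have excluded it, since all 10 lower is the most extreme lower outcome. A response to the control construct, which would raise these genes in the control cells, and an effect of Foxo4 knockdown cannot be told apart with 1 kind of control shRNA. If the ratio is turned, these genes would be higher in the Foxo4 shRNA cells, and a construct response would lie there.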
